A study of Mus musculus with 24 samples.

How the data were processed

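Liver RNA was extracted with Trizol and sequenced from TruSeq stranded mRNA libraries, per the labels. The 24 libraries form 8 groups of 3, made of 4 genotypes on 2 diets. The deposited table holds gene-level TPM, the share of transcripts taken by a gene scaled to the same total in each library, which the authors computed; the submitters' processing notes name kallisto and the builds GRCm38 and mm10. The version of kallisto and the annotation are not given in the sources used here. The table has 34945 named genes and 1 line without a name, which held 0.00994% to 0.0248% of the TPM and was left out. The listed TPM of a library summed to between 956785 and 993524, and 13131 genes were at 0 in every library.

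TPM are already divided by library total and transcript length, so they keep no read counts. The precision of a value was judged from the spread of 3 libraries. Values were used as deposited, without a further normalisation, and changed to log2(TPM + 1). Genes with a mean TPM of at least 1 over all libraries were tested, which left 10551. Foxo1 and Ppara positions were taken from the GENCODE M21 annotation of GRCm38, which may differ from the annotation the authors used.

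Groups were compared with limma 3.58.1 in R 4.3.3, with a mean per group in 1 fit of all 24 libraries (16 residual degrees of freedom) and variances moderated along a trend in expression. The 16 comparisons were each knockout against the floxed WT livers on each diet, the double knockout against either single knockout, the departure of the double knockout from the sum of both single knockouts, the high-fat against the regular diet in WT livers, and the genotype by diet interaction of each knockout. Benjamini-Hochberg adjustment was made within a comparison, and genes with an adjusted p under 0.05 were called. No replicate block was used, since the labels do not say what a replicate number shares. All p-values are two-sided. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so none was used for single genes.

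The comparisons, the tests, 36 gene lists with 533 distinct members and the rule for naming genes were fixed before the data were examined. The lists cover liver pathways, genes that differ between male and female liver, markers of the cell types a piece of liver could hold, and signs of RNA quality. Each list was tested against all other genes with camera from limma, with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists within a comparison.

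Foxo1 and Ppara were named first. In each comparison of a knockout with WT, the 10 highest and 10 lowest log2 fold changes were taken among called genes whose groups did not overlap, with a mean TPM of at least 5 in the higher group and a symbol other than a predicted or clone name. The first 5 each way were named and others could be. The other comparisons took 5 each way, interaction terms without the condition on overlap. For a described list, up to 4 members with the smallest adjusted p and any member against the list's direction could be named, and a gene named in 1 comparison could be given its value in others. Among genes with 3 against 3 libraries, chance alone separates both groups in 10% of cases. Cebpe, Cyp2a5 and the genes that separate all WT from all knockout libraries were chosen after their values were seen.

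Alternatives were a pseudocount of 0.1, no filter, a mean TPM of at least 5, rescaling by median-of-ratios factors, the compared groups alone in the fit, a replicate block, and leaving out each library in turn. Leaving out Mup and mitochondrial-genome transcripts before rescaling was added after the data were seen. The fit was tested on simulated data with 200 planted genes among 10551. It called 86% of planted log2 changes of 1 and 99% of 2 for LFKO on the regular diet, with 7 false calls among 192. For LFKO by diet it called 66% and 94%, with 12 false calls among 172. Camera called a list planted with a shift of 0.5 and 0 of 35 others. Real genes correlate, so these rates may not apply. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.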

Results

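RNA from the liver of mice was sequenced as polyadenylated, strand-marked libraries, and expression is given as gene-level TPM, the share of transcripts taken by a gene, for 24 libraries. Floxed mice without a stated Cre transgene (WT) were compared with liver knockouts made with Albumin-Cre, which is active in hepatocytes. The knockouts lacked the transcription factor FoxO1 (LFKO), the nuclear receptor PPARα (LPKO) or both (LFPKO), as labelled. Mice received a regular diet (RD) or a high-fat diet (HFD) for 3 weeks and were fasted for 4 h, giving 8 groups of 3 libraries. The labels number the replicates of a group and do not say that each came from a separate mouse, so p-values measure the spread between these samples. TPM keeps no record of sequencing depth, which is therefore unknown. Between 9749 and 10937 genes per library reached 1 TPM, and the correlation across genes of log2(TPM + 1) between libraries of a group was 0.970 to 0.991. Levels below are mean TPM ± SD with n = 3, and changes, also those in parentheses, are log2 fold changes (log2FC) ± SE on the log2(TPM + 1) scale, which understates changes of weakly expressed genes. Genes called changed passed a limma adjusted p of 0.05 among 10551 tested genes. Gene lists were fixed before the data were examined, and were tested against all other genes with camera, with a preset correlation between genes (camera p) and with an estimated one (estimated-correlation p), both adjusted over the lists. Counts of list members are of those tested, list medians are of log2FC, scaling means division by median-of-ratios size factors, and mt transcripts are those of the mitochondrial genome.

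The share of TPM taken by the Mup genes, which encode major urinary proteins, was 9.34% ± 1.96 in RD WT livers, 5.94% ± 0.901 in RD LFKO, 24.3% ± 4.90 in HFD WT and 11.6% ± 5.52 in HFD LFKO livers (SD, n = 3). The first principal component held 34.0% of the variance and the second 15.7%. HFD LFKO libraries lay far apart on the first component, at 22.0, -3.53 and -14.9 for replicates 1, 2 and 3. Mup genes, and likewise Cyp4a10, Cyp4a14, Cyp4a31 and Cyp4a32, Cyp2a4 and Cyp2a5, and Cyp2c40 and Cyp2c69, belong to families of similar genes, so the division of reads among members of each family is uncertain. How alike their sequences are was not measured here.

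**Figure D1:**
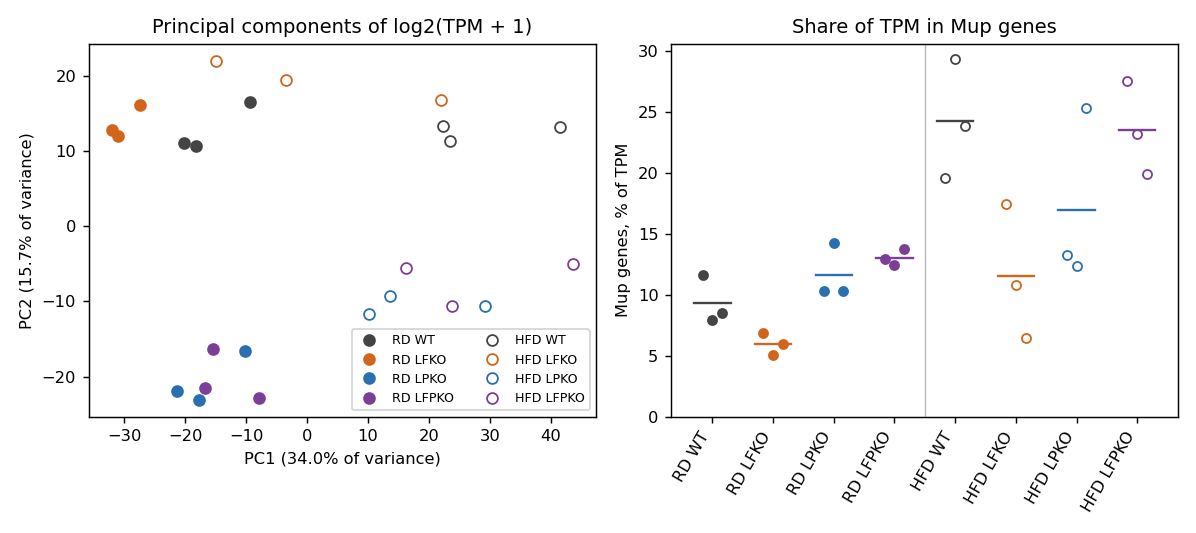
Left, each library at its scores on the first and second principal components of log2(TPM + 1) over the tested genes; right, the share of TPM in Mup genes in percent, with points for libraries and lines for means of 3. Filled points are regular-diet and open points high-fat-diet libraries, and HFD LFKO libraries spread from 22.0 to -14.9 on the first component.

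Foxo1 (chromosome 3, 52268336 to 52353221, plus strand, GRCm38, GENCODE M21) was nearly absent from the FoxO1 knockouts. It stood at 4.31 ± 0.206 TPM in RD WT and 0.400 ± 0.0883 TPM in RD LFKO livers (-1.92 ± 0.14, limma adjusted p = 6.88e-08). The highest value among the 12 LFKO and LFPKO libraries was 0.484 TPM and the lowest among the other 12 was 4.06 TPM, an 8.39-fold gap. On the high-fat diet Foxo1 was 4.77 ± 0.729 TPM in WT and 8.28 ± 2.40 TPM in LPKO livers (0.66 ± 0.14, limma adjusted p = 0.0107). Ppara (chromosome 15, 85734983 to 85802819, plus strand) was not lower in the 12 libraries labelled LPKO or LFPKO, which ranged from 57.5 to 87.3 TPM, than in the other 12, at 37.1 to 68.8 TPM. Its value was higher in HFD LPKO than in HFD WT livers (0.90 ± 0.14, limma adjusted p = 5.08e-04). A TPM summed over the whole gene includes transcripts that lack a deleted exon, and the deleted part is not given in the sources used here, so Ppara does not check the PPARα labels. Directions drawn from LPKO and LFPKO below refer to the libraries so labelled.

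**Figure D2:**
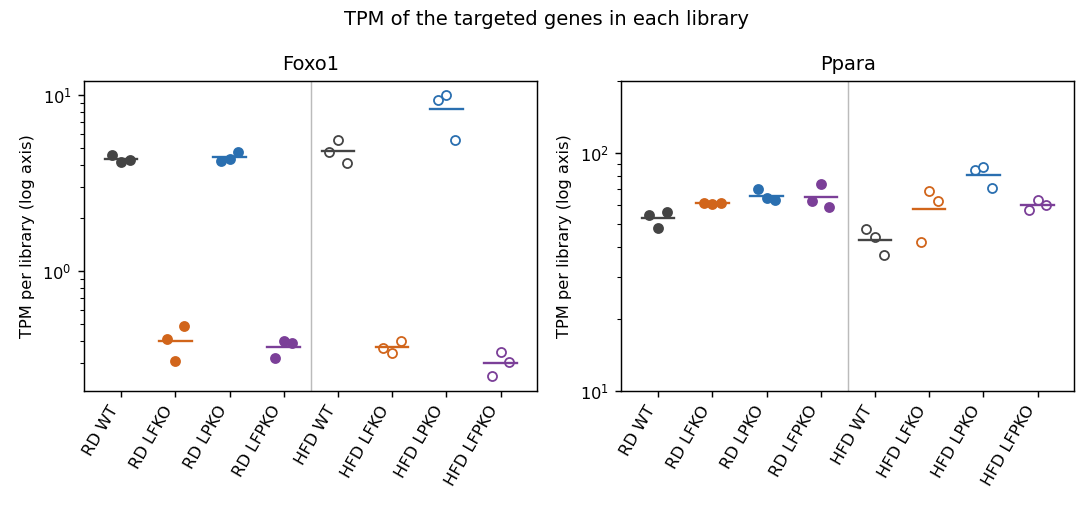
TPM of Foxo1 and Ppara in each of the 24 libraries on a log axis, by group, with points for libraries and lines for group means of 3; filled points are regular-diet and open points high-fat-diet libraries. Foxo1 stayed at or below 0.484 TPM in the LFKO and LFPKO libraries and at or above 4.06 TPM in the others, while Ppara lay between 37.1 and 87.3 TPM in all groups.

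On the regular diet, LFKO livers, which lack FoxO1 alone, had higher Cyp2b9 and Cyp2a4 and lower Mup7 than WT livers. Cyp2b9, a cytochrome P450 gene more active in female liver, went from 1.90 ± 0.825 TPM to 83.9 ± 35.8 TPM (4.82 ± 0.68, limma adjusted p = 4.82e-04). Cyp2a4, a steroid 15α-hydroxylase, went from 0.172 ± 0.0496 TPM to 231 ± 3.06 TPM (7.63 ± 1.17, limma adjusted p = 9.25e-04). Also higher were Cyp2c40 (4.13 ± 0.61), Cyp2c69 (3.62 ± 0.36), Tcf24 (2.88 ± 0.21), Cyp2a22 (2.43 ± 0.61), Slc22a26 (2.19 ± 0.34), the lipogenic gene Thrsp (2.0 ± 0.45), the peroxisomal fatty acid transporter gene Abcd2 (1.95 ± 0.38) and the immediate early gene Jun (1.91 ± 0.34, limma adjusted p at most 0.0494). Among the genes that fell, Mup7 went from 9538 ± 2772 TPM to 463 ± 134 TPM (-4.36 ± 0.79, limma adjusted p = 0.00471). Mup21 (-3.90 ± 0.44), the translation repressor gene Eif4ebp3 (-3.20 ± 0.32), Erdr1 (-3.16 ± 0.70), Mup1 (-3.10 ± 0.45), Mup12 (-3.08 ± 0.38), the oxysterol hydroxylase gene Cyp7b1 (-2.78 ± 0.51) and Slc15a5 (-2.77 ± 0.61, limma adjusted p at most 0.0240) fell with it. Cebpe was listed at 0 in all 3 LFKO libraries against 5.65 ± 1.96 TPM in WT.

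In the list of male-biased liver genes, 1 of 16 was called higher and 6 lower (1 and 7 adjusted over the list alone). The median was -0.94 (camera p = 4.43e-08, estimated-correlation p = 0.480). The member that rose was the organic anion transporter gene Slco1a1 (1.04 ± 0.19, limma adjusted p = 0.00476). Of the female-biased genes, 2 of 6 were called higher and 0 lower (2 and 0 adjusted over the list alone). The median was 1.55 (camera p = 0.00138, estimated-correlation p = 0.629). The interferon response list was higher by the set test, and its called member was Isg15 (0.98 ± 0.19, limma adjusted p = 0.00853): 1 of 17 was called higher and 0 lower (5 and 0 adjusted over the list alone). The median was 0.44 (camera p = 1.11e-05, estimated-correlation p = 0.646). Among other PPARα target genes, the hormone gene Fgf21 rose by 1.91 ± 0.25 (limma adjusted p = 1.63e-04), and for the list 2 of 18 were called higher and 0 lower (4 and 0 adjusted over the list alone). The median was 0.18 (camera p = 0.0362, estimated-correlation p = 0.668; set call lost after scaling). Markers of Kupffer cells, the resident macrophages of liver, were lower by the set test (median -0.38, camera p = 6.79e-04, estimated-correlation p = 0.668). Immediate early genes (median 0.67, camera p = 4.44e-05, 1 of 9 called, 5 adjusted over the list alone) and hepatocyte markers (median 0.23, camera p = 0.0243) were higher and mt transcripts (median -0.18, camera p = 3.36e-04, 1 adjusted over the list alone) lower, with estimated-correlation p at least 0.480. In all 113 genes were higher and 63 lower in LFKO than in WT livers, and none of the 14 list calls held with an estimated correlation. The count was 97 at a mean TPM of at least 5, 389 after scaling, 292 (121 higher, 171 lower) without Mup and mt transcripts and 431 with the compared groups alone in the fit. Leaving out 1 library gave 173 (68 higher, 105 lower), 105 and 81 without RD WT replicate 1, 2 and 3 and 94, 77 and 79 (37 higher, 42 lower) without RD LFKO replicate 1, 2 and 3.

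Livers labelled LPKO on the regular diet had lower Cyp4a14 and Vnn1 than WT livers. Cyp4a14, which encodes a fatty acid omega-hydroxylase, went from 526 ± 263 TPM to 21.4 ± 15.4 TPM (-4.66 ± 0.70, limma adjusted p = 2.81e-04). Vnn1, the gene for the pantetheinase vanin 1, went from 40.2 ± 18.3 TPM to 2.09 ± 0.754 TPM (-3.68 ± 0.33, limma adjusted p = 6.96e-07). Also lower were Cyp4a10 (-3.95 ± 0.55), the lysolipid transporter gene Mfsd2a (-3.39 ± 0.58), the lipid droplet gene Fitm1 (-3.23 ± 0.40), Cyp4a32 (-3.16 ± 0.24), Serpina7 (-2.54 ± 0.52), Cda (-2.49 ± 0.29), Lgals4 (-2.39 ± 0.30) and Rab30 (-2.33 ± 0.21, limma adjusted p at most 0.00452). The genes that rose most included the calcium-binding protein gene Cib3, from 4.79 ± 1.90 TPM to 135 ± 42.3 TPM (4.56 ± 0.48, limma adjusted p = 4.08e-06), and the apolipoprotein gene Apoa4, from 35.5 ± 17.3 TPM to 184 ± 67.2 TPM (2.38 ± 0.32, limma adjusted p = 9.48e-05). Higher as well were Cyp2a4 (6.50 ± 1.17), the adaptor gene Blnk (3.01 ± 0.24), the nicotinic acid receptor gene Hcar2 (2.25 ± 0.35), Apol9a (2.11 ± 0.27), Jun (2.10 ± 0.34), the fatty acid binding protein gene Fabp5 (2.09 ± 0.58), Usp18 (2.09 ± 0.22) and Gstm3 (1.85 ± 0.31, limma adjusted p at most 0.0347).

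Mitochondrial fatty acid oxidation genes fell together in the LPKO livers: 0 of 19 were called higher and 13 lower (0 and 14 adjusted over the list alone). The median was -0.69 (camera p = 1.47e-21, estimated-correlation p = 0.121). The electron transfer gene Etfdh fell by 1.18 and the carnitine transporter gene Slc25a20 by 1.75 on the log2 scale (limma adjusted p at most 1.68e-06). In the peroxisomal list, led by Decr2 (-1.78 ± 0.15), Ech1 (-1.39 ± 0.19) and Hsd17b4 (-0.92 ± 0.13, limma adjusted p at most 2.09e-04), 0 of 18 were called higher and 10 lower (0 and 14 adjusted over the list alone). The median was -0.86 (camera p = 9.71e-16, estimated-correlation p = 0.128). In the microsomal fatty acid hydroxylation list, 0 of 9 were called higher and 6 lower (0 and 6 adjusted over the list alone). The median was -1.26 (camera p = 1.35e-10, estimated-correlation p = 0.0289), the 1 list call of this comparison that held. Of other PPARα target genes, 1 of 18 was called higher and 7 lower (2 and 12 adjusted over the list alone). The median was -0.70 (camera p = 4.46e-10, estimated-correlation p = 0.121; 2 higher and 11 lower after scaling); the pyruvate dehydrogenase kinase gene Pdk4 went the other way (1.41 ± 0.34, limma adjusted p = 0.0155). Interferon response genes were higher, with Irf7 (1.34 ± 0.20), Isg15 (1.12 ± 0.19) and Ifit1 (0.91 ± 0.19): 10 of 17 were called higher and 0 lower (11 and 0 adjusted over the list alone). The median was 0.83 (camera p = 6.38e-10, estimated-correlation p = 0.258). Genes of cholesterol synthesis and uptake were higher too, with Sqle (1.27 ± 0.26) and Mvd (1.04 ± 0.23): 6 of 22 were called higher and 0 lower (16 and 0 adjusted over the list alone). The median was 0.71 (camera p = 8.11e-09, estimated-correlation p = 0.369; 10 higher and 0 lower after scaling). Kupffer cell markers were lower in the same livers (median -0.80, camera p = 1.47e-08, estimated-correlation p = 0.369), with Cd163 called (-1.01 ± 0.29, limma adjusted p = 0.0444) and 14 of 14 lower adjusted over the list alone. Immediate early genes (median 0.86, camera p = 0.00103, 3 of 9 called) were higher and mt transcripts (median -0.31, camera p = 6.79e-06, 4 adjusted over the list alone) lower, with estimated-correlation p at least 0.369. In all 371 genes were higher and 246 lower. This count became 952 after scaling and 949 without Mup and mt transcripts. Single libraries moved the count, to 414 (185 higher, 229 lower) without RD WT replicate 1 and 326 (161 higher, 165 lower) and 312 without RD LPKO replicate 1 and 3.

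LFPKO livers on the regular diet, labelled as lacking both factors, had lower G6pc and Cyp2c37 than WT livers. G6pc, whose enzyme, glucose-6-phosphatase, catalyses the last step of glucose release, was 209 ± 28.4 TPM in WT and 37.9 ± 13.6 TPM in LFPKO livers (-2.48 ± 0.35, limma adjusted p = 9.94e-05), with 82.0 ± 24.7 TPM in LFKO and 83.0 ± 9.88 TPM in LPKO livers. The P450 gene Cyp2c37 went from 226 ± 15.5 TPM to 45.5 ± 22.1 TPM (-2.38 ± 0.33, limma adjusted p = 9.36e-05). Cyp4a10 (-4.31 ± 0.55), Cyp4a14 (-4.02 ± 0.70), Cyp4a32 (-3.90 ± 0.24), Fitm1 (-3.28 ± 0.40), Vnn1 (-3.0 ± 0.33), Mfsd2a (-2.71 ± 0.58), Cda (-2.50 ± 0.29) and Lgals4 (-2.47 ± 0.30, limma adjusted p at most 0.00507) fell as well. On the other side, Apoa4 reached 323 ± 124 TPM (3.16 ± 0.32, limma adjusted p = 2.95e-06) and the citrate transporter gene Slc13a5 rose from 0.215 ± 0.0942 TPM to 6.33 ± 2.01 TPM (2.56 ± 0.30, limma adjusted p = 1.20e-05). Cyp2a4 (7.42 ± 1.17), Cib3 (4.04 ± 0.48), Blnk (2.97 ± 0.24), Nat8f7 (2.95 ± 0.54), Hcar2 (2.52 ± 0.35) and the stress hormone gene Gdf15 (2.39 ± 0.62, limma adjusted p at most 0.0207) were also higher.

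For mitochondrial fatty acid oxidation in the LFPKO livers, 0 of 19 were called higher and 12 lower (0 and 14 adjusted over the list alone). The median was -0.58 (camera p = 7.67e-17, estimated-correlation p = 0.181). The acyl-CoA synthetase gene Acsl1 was among them (-1.53 ± 0.17, limma adjusted p = 6.43e-06). Peroxisomal genes fell with them: 0 of 18 were called higher and 9 lower (0 and 14 adjusted over the list alone). The median was -0.87 (camera p = 1.33e-11, estimated-correlation p = 0.237). In the microsomal hydroxylation list, 0 of 9 were called higher and 6 lower (0 and 7 adjusted over the list alone). The median was -1.39 (camera p = 5.03e-10, estimated-correlation p = 0.0390), again the list call that held. Interferon response genes were higher, with Usp18 (1.82 ± 0.22), Irf7 (1.44 ± 0.20) and Ifit1 (1.33 ± 0.19): 11 of 17 were called higher and 0 lower (12 and 0 adjusted over the list alone). The median was 0.96 (camera p = 2.55e-13, estimated-correlation p = 0.181). The list of cholesterol synthesis and uptake was higher (median 0.64, camera p = 9.59e-06, estimated-correlation p = 0.508). Kupffer cell markers were lower (median -0.74, camera p = 8.68e-06, estimated-correlation p = 0.508), and so were transcripts of the mitochondrial genome, with 4 of 13 called (median -0.31, camera p = 1.30e-06, estimated-correlation p = 0.349). In all 422 genes were higher and 364 lower. Calls numbered 1322 after scaling, 1225 without Mup and mt transcripts and 682 (335 higher, 347 lower) with the compared groups alone in the fit. With 1 library left out there were 645 (253 higher, 392 lower) and 480 without RD WT replicate 1 and 3 and 417 without RD LFPKO replicate 3.

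Setting LFPKO against LFKO livers asks what the PPARα deletion changed where FoxO1 was already absent. On the regular diet Cyp2b9 was 0.926 ± 1.22 TPM in LFPKO against 83.9 ± 35.8 TPM in LFKO livers (-5.55 ± 0.68, limma adjusted p = 2.01e-05), with Cyp2c40 (-5.19 ± 0.61) and Cyp2c69 (-4.68 ± 0.36, limma adjusted p at most 1.34e-05) lower too. Cyp2a4 was 269 ± 237 TPM against 231 ± 3.06 TPM (limma adjusted p = 0.959), and 1 of 6 female-biased genes was called lower (median -0.34, camera p = 0.115, estimated-correlation p = 0.820). Mup7 was 12519 ± 2651 TPM against 463 ± 134 TPM, and the higher genes were Mup7 (4.78 ± 0.79), Mup20 (3.07 ± 0.39), Mup21 (2.96 ± 0.44), Cib3 (3.57 ± 0.48) and Nat8f5 (3.42 ± 0.47, limma adjusted p at most 5.88e-04). The lower ones included Cyp4a14 (-4.58 ± 0.70) and Cyp4a10 (-3.99 ± 0.55, limma adjusted p at most 2.33e-04). Of mitochondrial fatty acid oxidation genes, 0 of 19 were called higher and 15 lower (0 and 16 adjusted over the list alone). The median was -0.96 (camera p = 5.80e-28, estimated-correlation p = 0.0477). Of other PPARα target genes, among them Vnn1 (-3.82 ± 0.33), Fgf21 (-2.84 ± 0.25) and Retsat (-1.85 ± 0.25, limma adjusted p at most 6.02e-05), 0 of 18 were called higher and 11 lower (0 and 13 adjusted over the list alone). The median was -0.90 (camera p = 4.37e-13, estimated-correlation p = 0.0477). The microsomal hydroxylation list was the third whose call held (median -1.57, camera p = 1.79e-08, estimated-correlation p = 0.0477). For male-biased liver genes, 6 of 16 were called higher and 0 lower (8 and 0 adjusted over the list alone). The median was 0.52 (camera p = 4.95e-08, estimated-correlation p = 0.154). In all 206 genes were higher and 330 lower. The count was 885 after scaling and 992 (620 higher, 372 lower) without Mup and mt transcripts. Leaving out 1 library gave 310 and 330 without RD LFKO replicate 1 and 3 and 278 without RD LFPKO replicate 3.

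The reverse comparison, LFPKO against LPKO livers, asks what the FoxO1 deletion changed where PPARα was absent by label. On the regular diet few genes passed. Cyp8b1, the sterol 12α-hydroxylase of bile acid synthesis, was 69.7 ± 21.8 TPM in LFPKO and 346 ± 64.7 TPM in LPKO livers (-2.32 ± 0.36, limma adjusted p = 0.00428). The succinate receptor gene Sucnr1 was 4.21 ± 0.932 TPM against 20.02 ± 3.94 TPM (-2.01 ± 0.27, limma adjusted p = 8.92e-04). Eif4ebp3 (-2.03 ± 0.32), H2ac18 (-1.79 ± 0.34) and Tbc1d30 (-1.65 ± 0.19, limma adjusted p at most 0.0405) were lower too, and the bile acid transporter gene Slc10a2 was higher (1.49 ± 0.27, limma adjusted p = 0.0258). Foxo1 was lower (-1.98 ± 0.14, limma adjusted p = 1.20e-07). By the set test the 2 tested lymphocyte markers (median 1.06, camera p = 0.00218, 2 adjusted over the list alone), cell proliferation genes (median 0.20, camera p = 0.00218) and interferon response genes (median 0.09, camera p = 0.00524) were higher and immediate early genes (median -0.49, camera p = 0.0238, 1 adjusted over the list alone) and amino acid breakdown and urea cycle genes (median -0.16, camera p = 0.00218, 1 adjusted over the list alone) lower, with estimated-correlation p at least 0.0758; 0 members were called. In all 2 genes were higher and 11 lower. This count became 8 with a pseudocount of 0.1, 4 at a mean TPM of at least 5 and 8 with the compared groups alone in the fit. Single libraries moved the count, to 7 without RD LPKO replicate 3. After scaling there were 4 and 11, and H2ac18 was not called.

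Whether the deletions added up was tested as the change in LFPKO minus the changes in LFKO and LPKO, all against WT on the log2 scale, where 0 is additivity. Below additivity were Cyp2c40 (-4.81 ± 0.86), Cyp2c69 (-4.12 ± 0.51), H2ac18 (-2.60 ± 0.49), Tcf24 (-2.52 ± 0.30) and Jun (-2.40 ± 0.49, limma adjusted p at most 0.0338). Cyp2c69 was 1.99, 36.6, 0.948 and 0.317 TPM in WT, LFKO, LPKO and LFPKO livers. Above additivity were Mup21 (3.45 ± 0.63), Mup12 (3.09 ± 0.54), Nat8 (2.93 ± 0.42), the receptor inhibitor gene Errfi1 (1.76 ± 0.33) and the NADPH oxidase gene Nox4 (1.0 ± 0.20, limma adjusted p at most 0.0298). For immediate early genes, 0 of 9 were called higher and 1 lower (0 and 4 adjusted over the list alone). The median was -1.11 (camera p = 4.95e-08, estimated-correlation p = 0.185). For male-biased liver genes, 1 of 16 was called higher and 0 lower (7 and 1 adjusted over the list alone). The median was 0.63 (camera p = 1.03e-06, estimated-correlation p = 0.534). Kupffer cell markers (median 0.47, camera p = 4.65e-05) and mt transcripts (median 0.10, camera p = 0.0293) lay above additivity, with estimated-correlation p at least 0.830. In all 8 genes lay above and 19 below additivity. Calls numbered 16 with a pseudocount of 0.1, 14 at a mean TPM of at least 5 and 74 with the compared groups alone in the fit. With 1 library left out there were 25 (14 above, 11 below), 13 and 12 without RD WT replicate 1, 2 and 3, 10 and 13 without RD LFKO replicate 2 and 3, 8 without RD LPKO replicate 3 and 16, 13 and 16 without RD LFPKO replicate 1, 2 and 3.

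On the high-fat diet, LFKO livers had higher Cyp4a14 and Scd1 and lower Mup7 than WT livers. Cyp4a14 was 467 ± 316 TPM against 16.1 ± 12.1 TPM (4.81 ± 0.70, limma adjusted p = 4.63e-04), and Scd1, the stearoyl-CoA desaturase gene, was 562 ± 249.5 TPM against 102 ± 73.8 TPM (2.85 ± 0.66, limma adjusted p = 0.0118). The fatty acid transporter gene Cd36 rose from 4.35 ± 1.06 TPM to 36.5 ± 24.8 TPM (2.55 ± 0.41, limma adjusted p = 0.00121). Higher too were Cyp2b9 (4.62 ± 0.68), Cyp2a4 (3.96 ± 1.17), Abcd2 (2.48 ± 0.38), the monocarboxylate transporter gene Slc16a5 (2.46 ± 0.50), Cyp2a22 (2.43 ± 0.61), the acyl-CoA thioesterase genes Acot3 (4.76 ± 0.99) and Acot4 (2.52 ± 0.48, limma adjusted p at most 0.0320), although Cyp2a4 lost its call after scaling. Mup7 fell from 58508 ± 9081 TPM to 15730.0 ± 19450.0 TPM (-3.14 ± 0.79, limma adjusted p = 0.0166), with Mup1 (-2.48 ± 0.45), Mup14 (-2.10 ± 0.51), Mup12 (-1.97 ± 0.38), Mup21 (-1.91 ± 0.44), Mup16 (-1.88 ± 0.38), Erdr1 (-2.74 ± 0.70), Cyp7b1 (-1.82 ± 0.51), Mup-ps8 (-1.98 ± 0.45) and Mup-ps17 (-2.09 ± 0.61, limma adjusted p at most 0.0301). Among these, Mup-ps17 lost its call after scaling.

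Genes of cholesterol synthesis and uptake rose together in HFD LFKO livers, led by the demethylase gene Cyp51 (1.66 ± 0.18), Nsdhl (1.73 ± 0.19), Sqle (2.15 ± 0.26) and Idi1 (2.09 ± 0.25, limma adjusted p at most 7.21e-05): 20 of 22 were called higher and 0 lower (22 and 0 adjusted over the list alone). The median was 1.15 (camera p = 3.24e-19, estimated-correlation p = 0.211). The male-biased list was lower, with the glutathione transferase gene Gstp1 (-1.52 ± 0.26, limma adjusted p = 0.00210), and was the list call that held: 0 of 16 were called higher and 8 lower (1 and 9 adjusted over the list alone). The median was -0.96 (camera p = 1.17e-21, estimated-correlation p = 0.0170). Of female-biased genes, 5 of 6 were called higher and 0 lower (6 and 0 adjusted over the list alone). The median was 2.92 (camera p = 9.50e-05, estimated-correlation p = 0.211; 3 higher and 0 lower after scaling); the flavin monooxygenase gene Fmo2 was one (1.89 ± 0.28, limma adjusted p = 4.63e-04). For mitochondrial fatty acid oxidation, 12 of 19 were called higher and 0 lower (16 and 0 adjusted over the list alone). The median was 0.49 (camera p = 2.04e-05, estimated-correlation p = 0.479; 2 higher and 0 lower, median 0.25 after scaling), and peroxisomal genes were higher too (median 0.53, camera p = 3.17e-05, estimated-correlation p = 0.479; 5 higher and 0 lower, median 0.29 after scaling). The FoxO1 target list was lower than other genes by the set test although its median was above 0: 1 of 19 was called higher and 2 lower (1 and 2 adjusted over the list alone). The median was 0.16 (camera p = 0.00415, estimated-correlation p = 0.237; median -0.08 after scaling, set call lost). G6pc was 57.7 ± 24.2 TPM against 179 ± 40.1 TPM (-1.67 ± 0.35, limma adjusted p = 0.00613), Igfbp1 was lower (-1.98 ± 0.62, limma adjusted p = 0.0391) and the sestrin gene Sesn1 higher (0.68 ± 0.19, limma adjusted p = 0.0266); scaling ended both calls. Stellate cell and matrix genes were higher in the same livers (median 0.62, camera p = 0.00376, estimated-correlation p = 0.479; 0 higher and 0 lower after scaling), with Col4a1 (0.95 ± 0.22) and Dcn (0.74 ± 0.19, limma adjusted p at most 0.0159). Hepatocyte markers (median 0.36, camera p = 0.0493, 4 of 10 called, 5 adjusted over the list alone, set call lost after scaling) were higher and erythroid markers (median -0.45, camera p = 0.00511, set call lost after scaling) and immediate early genes (median -0.21, camera p = 0.00376, 1 of 9 called higher, set call lost after scaling) lower, with estimated-correlation p at least 0.463. The immediate early gene called higher was Zfp36 (0.76 ± 0.24, limma adjusted p = 0.0442), lost after scaling. In all 1343 genes were higher and 77 lower. The count was 440 (203 higher, 237 lower) without Mup and mt transcripts and 140 with the compared groups alone in the fit. Leaving out 1 library gave 199 without HFD WT replicate 2 and 3501, 310 and 238 without HFD LFKO replicate 1, 2 and 3. The median of all genes shifted by 0.21, and after scaling 269 genes were higher and 181 lower.

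In livers labelled LPKO on the high-fat diet, cholesterol synthesis genes were among those that rose most. The squalene epoxidase gene Sqle was 47.2 ± 14.1 TPM against 4.34 ± 0.933 TPM in WT livers (3.15 ± 0.26, limma adjusted p = 1.97e-07), and Hmgcs1, the cytosolic HMG-CoA synthase gene, 114 ± 28.7 TPM against 15.8 ± 1.70 TPM (2.74 ± 0.31, limma adjusted p = 9.60e-06). Fdps (2.92 ± 0.25), Idi1 (2.86 ± 0.25), Msmo1 (2.64 ± 0.24) and Cyp51 (2.58 ± 0.18, limma adjusted p at most 8.52e-07) rose with them: 20 of 22 were called higher and 0 lower (22 and 0 adjusted over the list alone). The median was 1.84 (camera p = 4.12e-39, estimated-correlation p = 0.0322), which was the list call that held. Other genes that rose were Scd1 (3.08 ± 0.66), Apoa4 (2.92 ± 0.32), the metallothionein gene Mt2 (2.97 ± 0.69) and the neprilysin gene Mme (2.62 ± 0.28, limma adjusted p at most 0.0143). Vnn1 fell from 26.4 ± 0.985 TPM to 1.85 ± 1.33 TPM (-3.38 ± 0.33, limma adjusted p = 1.73e-06), and the carboxylesterase gene Ces4a from 8.03 ± 3.43 TPM to 0.673 ± 0.258 TPM (-2.36 ± 0.31, limma adjusted p = 6.60e-05). Cyp4a32 (-2.65 ± 0.24), Fitm1 (-2.35 ± 0.40), Mup1 (-1.98 ± 0.45), Rarres1 (-1.95 ± 0.28), Mup12 (-1.90 ± 0.38), Decr2 (-1.88 ± 0.15), Lgals4 (-1.72 ± 0.30) and Qpct (-1.69 ± 0.13, limma adjusted p at most 0.0127) were lower.

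Mitochondrial fatty acid oxidation genes fell in the HFD LPKO livers, with Etfdh (-1.23 ± 0.11) and Acadvl (-1.15 ± 0.13, limma adjusted p at most 7.29e-06): 0 of 19 were called higher and 10 lower (2 and 12 adjusted over the list alone). The median was -0.49 (camera p = 1.81e-19, estimated-correlation p = 0.121). In the peroxisomal list, 1 of 18 was called higher and 5 lower (1 and 8 adjusted over the list alone). The median was -0.39 (camera p = 3.72e-10, estimated-correlation p = 0.402; 1 higher and 10 lower after scaling), and the higher member was Acot4 (1.67 ± 0.48, limma adjusted p = 0.0484). Among microsomal genes, Cyp4a31 fell with Cyp4a32 while Cyp4f14 rose (Cyp4a31 -1.10 ± 0.19 and Cyp4f14 0.78 ± 0.17, limma adjusted p at most 0.00958), and the list was lower (median -0.92, camera p = 3.64e-07, estimated-correlation p = 0.0764; 1 higher and 5 lower after scaling). Stellate cell and matrix genes were higher by the set test (median 0.51, camera p = 0.00229, estimated-correlation p = 0.628). In all 380 genes were higher and 119 lower. This count became 679 (291 higher, 388 lower) without Mup and mt transcripts and 147 with the compared groups alone in the fit. Single libraries moved the count, to 198 without HFD WT replicate 2 and 238, 264 and 889 without HFD LPKO replicate 1, 2 and 3. The median of all genes shifted by 0.11, and after scaling 388 genes were higher and 339 lower.

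With both deletions, as labelled, on the high-fat diet, Vnn1 was 0.702 ± 0.207 TPM against 26.4 ± 0.985 TPM in WT livers (-4.02 ± 0.33, limma adjusted p = 2.04e-07). G6pc was 26.6 ± 4.29 TPM against 179 ± 40.1 TPM (-2.70 ± 0.35, limma adjusted p = 4.36e-05), and Angptl4, the gene for an inhibitor of lipoprotein lipase, 14.4 ± 11.3 TPM against 66.4 ± 24.9 TPM (-2.30 ± 0.50, limma adjusted p = 0.00956). Also lower were Cyp4a10 (-3.76 ± 0.55), Cyp4a32 (-3.38 ± 0.24), Cnmd (-2.57 ± 0.28), the peroxisomal thiolase gene Acaa1b (-2.56 ± 0.39), Decr2 (-2.41 ± 0.15), Fitm1 (-2.38 ± 0.40) and Ces4a (-2.21 ± 0.31, limma adjusted p at most 9.62e-04). Apoa4 rose from 55.7 ± 9.35 TPM to 461 ± 42.4 TPM (3.04 ± 0.32, limma adjusted p = 5.84e-06), and Lcn2, the acute phase gene for lipocalin 2, from 9.48 ± 3.52 TPM to 61.7 ± 22.6 TPM (2.56 ± 0.37, limma adjusted p = 1.79e-04). Other increases were those of the steroid 17α-hydroxylase gene Cyp17a1 (2.38 ± 0.53), Nat8f7 (2.54 ± 0.54), Sqle (2.54 ± 0.26), Blnk (2.19 ± 0.24), Lrtm1 (2.17 ± 0.36), Hmgcs1 (2.15 ± 0.31), the metallothionein genes Mt1 (2.35 ± 0.49) and Mt2 (2.83 ± 0.69, limma adjusted p at most 0.0227).

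Mitochondrial fatty acid oxidation genes were lower in the HFD LFPKO livers: 0 of 19 were called higher and 11 lower (0 and 14 adjusted over the list alone). The median was -0.81 (camera p = 3.80e-29, estimated-correlation p = 0.0428). In the microsomal list, 0 of 9 were called higher and 5 lower (0 and 6 adjusted over the list alone). The median was -1.46 (camera p = 8.31e-14, estimated-correlation p = 0.00859), and both calls held. Peroxisomal genes fell as well (median -0.65, camera p = 1.79e-16, estimated-correlation p = 0.116). Of cholesterol synthesis and uptake genes, 14 of 22 were called higher and 0 lower (21 and 0 adjusted over the list alone). The median was 1.15 (camera p = 1.25e-25, estimated-correlation p = 0.0583). Interferon response genes rose, with Ifit1 (1.35 ± 0.19), Ifit3 (1.27 ± 0.21) and Rsad2 (0.94 ± 0.18): 8 of 17 were called higher and 0 lower (12 and 0 adjusted over the list alone). The median was 0.92 (camera p = 4.65e-12, estimated-correlation p = 0.131). Stellate cell and matrix genes (median 0.35, camera p = 0.0320) were higher and endothelial markers (median -0.19, camera p = 0.0302, set call lost after scaling) lower, with estimated-correlation p at least 0.638. In all 171 genes were higher and 155 lower. Calls numbered 251 (125 higher, 126 lower) at a mean TPM of at least 5, 587 (245 higher, 342 lower) without Mup and mt transcripts and 165 (76 higher, 89 lower) with the compared groups alone in the fit. With 1 library left out there were 227 (94 higher, 133 lower) without HFD WT replicate 2 and 217 (93 higher, 124 lower) and 274 (123 higher, 151 lower) without HFD LFPKO replicate 2 and 3. After scaling 236 genes were higher and 346 lower.

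**Figure D3:**
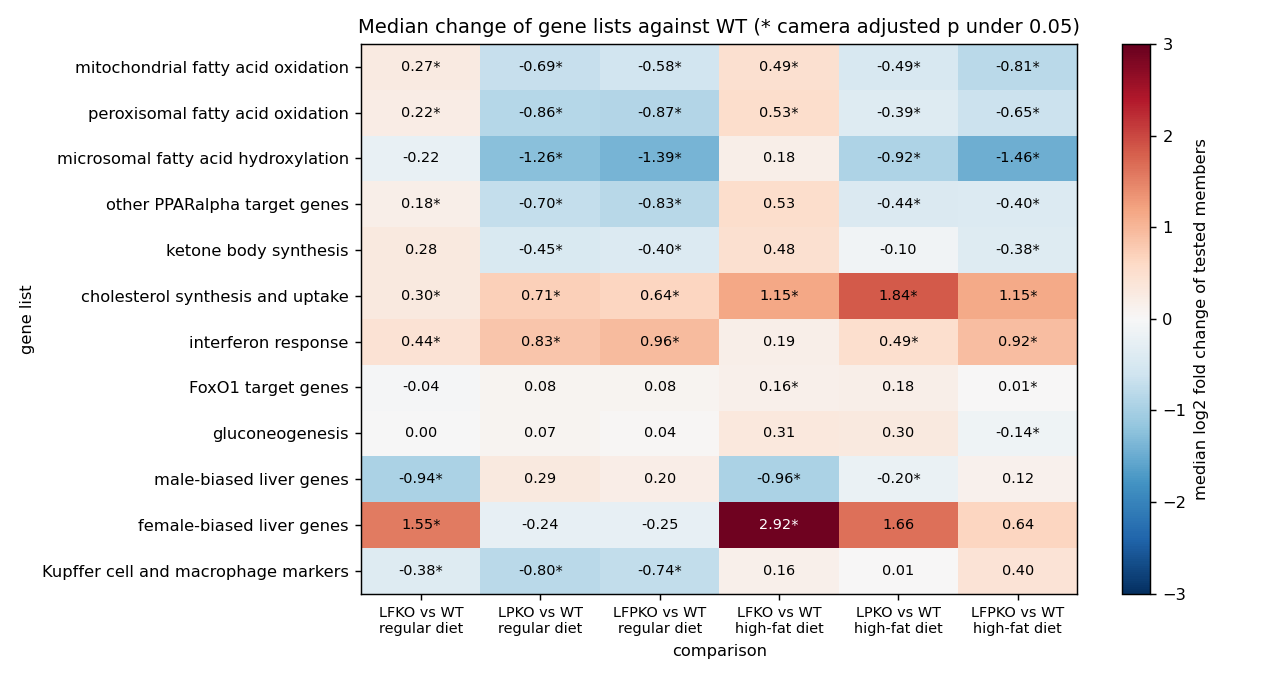
Median log2 fold change of the tested members of 12 gene lists (vertical) in the 6 comparisons of a knockout against WT (horizontal), in colour and as numbers; an asterisk marks a camera adjusted p under the threshold with the preset correlation. Mitochondrial fatty acid oxidation had medians of -0.69 and -0.81 in RD LPKO and HFD LFPKO livers, and cholesterol synthesis and uptake 1.84 in HFD LPKO livers.

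Against LFKO livers on the high-fat diet, LFPKO livers had lower Cyp4a14 and Vnn1. Cyp4a14 was 2.08 ± 1.79 TPM against 467 ± 316 TPM (-7.05 ± 0.70, limma adjusted p = 8.61e-07) and Vnn1 0.702 ± 0.207 TPM against 71.0 ± 21.9 TPM (-5.36 ± 0.33, limma adjusted p = 1.27e-09), with Cyp4a10 (-5.99 ± 0.55), Cyp2b9 (-4.99 ± 0.68) and Mfsd2a (-4.06 ± 0.58, limma adjusted p at most 7.13e-05) also lower. The estrogen sulfotransferase gene Sult1e1 was higher, at 28.7 ± 25.6 TPM against 0.939 ± 0.513 TPM (3.47 ± 0.73, limma adjusted p = 0.00341), as were Mup-ps20 (3.30 ± 0.57), Mup7 (3.17 ± 0.79), the serpin genes Serpine2 (2.63 ± 0.25) and Serpina12 (2.55 ± 0.33, limma adjusted p at most 0.0123). Of mitochondrial fatty acid oxidation genes, 0 of 19 were called higher and 18 lower (0 and 18 adjusted over the list alone). The median was -1.32 (camera p = 1.23e-26, estimated-correlation p = 0.0539). Of peroxisomal ones, 0 of 18 were called higher and 16 lower (0 and 16 adjusted over the list alone). The median was -1.55 (camera p = 1.41e-18, estimated-correlation p = 0.0775), and of male-biased liver genes, 8 of 16 were called higher and 0 lower (9 and 0 adjusted over the list alone). The median was 0.88 (camera p = 1.90e-13, estimated-correlation p = 0.0539). Kupffer cell markers (median 0.23, camera p = 0.00173) and immediate early genes (median 0.45, camera p = 0.0115, set call lost after scaling) were higher, with estimated-correlation p at least 0.475. In all 195 genes were higher and 922 lower. The count was 1170 (650 higher, 520 lower) without Mup and mt transcripts and 267 with the compared groups alone in the fit. Leaving out 1 library gave 2438, 606 and 551 without HFD LFKO replicate 1, 2 and 3 and 655 without HFD LFPKO replicate 1. The median of all genes shifted by -0.13, and after scaling 490 genes were higher and 657 lower.

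On the high-fat diet LFPKO livers were also compared with livers labelled LPKO, again for the effect of the FoxO1 deletion. The cyclin D1 gene Ccnd1 was 23.9 ± 6.84 TPM against 6.97 ± 1.44 TPM (1.62 ± 0.35, limma adjusted p = 0.0473), and the activin subunit gene Inhbe (1.48 ± 0.28) and the glypican gene Gpc1 (1.03 ± 0.22, limma adjusted p at most 0.0424) were higher too. Besides Foxo1 (-2.80 ± 0.14, limma adjusted p = 1.86e-10), the lower genes included Mme, at 0.270 ± 0.113 TPM against 6.17 ± 0.284 TPM (-2.50 ± 0.28, limma adjusted p = 6.64e-05), and Serpinb1a (-1.97 ± 0.35), Eif4ebp3 (-1.83 ± 0.32) and Cyp2c37 (-1.78 ± 0.33, limma adjusted p at most 0.0183). In the cholesterol synthesis and uptake list, with Nsdhl (-1.18 ± 0.19) and Cyp51 (-0.92 ± 0.18, limma adjusted p at most 0.0312), 0 of 22 were called higher and 4 lower (0 and 14 adjusted over the list alone). The median was -0.61 (camera p = 6.80e-13, estimated-correlation p = 0.301). For gluconeogenesis, 0 of 16 were called higher and 0 lower (0 and 10 adjusted over the list alone). The median was -0.40 (camera p = 3.86e-08, estimated-correlation p = 0.301); the values were -1.32 ± 0.35 for G6pc and -1.11 ± 0.30 for the phosphoenolpyruvate carboxykinase gene Pck1 (limma adjusted p = 0.118 and 0.127 over all genes). Kupffer cell markers (median 0.39, camera p = 2.69e-04) were higher and mt transcripts (median -0.21, camera p = 0.0318, set call lost after scaling) lower, with estimated-correlation p at least 0.568. In all 7 genes were higher and 30 lower. This count became 21 at a mean TPM of at least 5, 126 after scaling, 104 without Mup and mt transcripts and 5 with the compared groups alone in the fit. Single libraries moved the count, to 10, 15 and 283 without HFD LPKO replicate 1, 2 and 3 and 15, 8 and 99 without HFD LFPKO replicate 1, 2 and 3.

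Additivity was tested in the same way on the high-fat diet, with the same limit from Albumin-Cre. Scd1 was 102, 562, 776 and 237 TPM in WT, LFKO, LPKO and LFPKO livers (-4.39 ± 0.93, limma adjusted p = 0.00729). Cyp4a14, called higher in LFKO livers, was lowest in LFPKO livers (-6.13 ± 0.99, limma adjusted p = 0.00115). Acot3 (-5.80 ± 1.40), Hamp2 (-5.42 ± 1.64) and Cyp2b9 (-4.66 ± 0.96, limma adjusted p at most 0.0385) also lay below additivity, although Hamp2, a hepcidin gene, lost its call after scaling. Above additivity were Mup7 (4.08 ± 1.12), Mup1 (3.36 ± 0.63), Mup-ps17 (3.04 ± 0.86), Mup12 (2.90 ± 0.54) and Mup14 (2.86 ± 0.72, limma adjusted p at most 0.0284). Of cholesterol synthesis and uptake genes, 0 of 22 were called higher and 20 lower (0 and 22 adjusted over the list alone). The median was -1.75 (camera p = 2.50e-21, estimated-correlation p = 0.154). Of male-biased liver genes, 7 of 16 were called higher and 0 lower (9 and 0 adjusted over the list alone). The median was 1.27 (camera p = 7.25e-18, estimated-correlation p = 0.0424), the list call that held. Kupffer cell markers (median 0.29, camera p = 4.32e-04) and erythroid markers (median 0.08, camera p = 0.0295, set call lost after scaling) lay above additivity and hepatocyte markers (median -0.47, camera p = 0.0300, 3 of 10 called, 7 adjusted over the list alone, set call lost after scaling) and stellate cell and matrix genes (median -0.81, camera p = 0.00532, 4 of 11 called, 8 adjusted over the list alone) below it, with estimated-correlation p at least 0.482. In all 70 genes lay above and 1109 below additivity. Calls numbered 628 (341 above, 287 below) without Mup and mt transcripts and 130 with the compared groups alone in the fit. With 1 library left out there were 431 without HFD WT replicate 2, 2611, 543 and 465 without HFD LFKO replicate 1, 2 and 3, 512, 610 and 2034 without HFD LPKO replicate 1, 2 and 3 and 546 without HFD LFPKO replicate 1. The median of all genes shifted by -0.24, and after scaling 232 lay above and 419 below.

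In WT livers Cyp4a14 and Scd1 were lower and several Mup genes higher on the high-fat diet. Cyp4a14 went from 526 ± 263 TPM to 16.1 ± 12.1 TPM (-5.20 ± 0.70, limma adjusted p = 8.27e-05) and Scd1 from 1329 ± 415 TPM to 102 ± 73.8 TPM (-4.16 ± 0.66, limma adjusted p = 3.93e-04). They fell with the glutathione transferase gene Gsta2 (-4.13 ± 0.46), Cyp4a10 (-3.49 ± 0.55) and the glucuronosyltransferase gene Ugt1a5 (-3.22 ± 0.43, limma adjusted p at most 3.65e-04). Mup17 rose from 442 ± 716 TPM to 11779 ± 6193 TPM (6.76 ± 1.24, limma adjusted p = 0.00135), with Mup15 (6.83 ± 1.40), Mup9 (4.06 ± 0.91), Psenen-ps (2.80 ± 1.0) and Mup7 (2.65 ± 0.79, limma adjusted p at most 0.0401); Psenen-ps lost its call after scaling. Genes of cholesterol synthesis and uptake fell together, led by Cyp51 (-2.19 ± 0.18) and Fdps (-2.89 ± 0.25, limma adjusted p at most 1.04e-06): 0 of 22 were called higher and 22 lower (0 and 22 adjusted over the list alone). The median was -1.74 (camera p = 3.05e-23, estimated-correlation p = 0.0585). In the microsomal fatty acid hydroxylation list, 0 of 9 were called higher and 7 lower (0 and 7 adjusted over the list alone). The median was -1.01 (camera p = 0.00484, estimated-correlation p = 0.332; 0 higher and 3 lower after scaling). For xenobiotic metabolism, with Cyp2c55 (-2.01 ± 0.21) and Cyp2c29 (-2.54 ± 0.29, limma adjusted p at most 1.30e-05), 0 of 21 were called higher and 15 lower (0 and 18 adjusted over the list alone). The median was -1.36 (camera p = 1.50e-06, estimated-correlation p = 0.332; 0 higher and 9 lower after scaling). Interferon response genes were higher, Usp18 by 1.03 ± 0.22 and Isg15 by 0.82 ± 0.19 (limma adjusted p at most 0.00592), while Bst2 was lower (-0.43 ± 0.15, limma adjusted p = 0.0356): 5 of 17 were called higher and 1 lower (5 and 1 adjusted over the list alone). The median was 0.41 (camera p = 7.84e-19, estimated-correlation p = 0.0585; 8 higher and 0 lower, median 0.72 after scaling). Stellate cell and matrix genes were lower in the same livers, with 10 of 11 called (median -0.93, camera p = 2.43e-04, estimated-correlation p = 0.332; 0 higher and 6 lower, median -0.61 after scaling). The 1 tested pancreatic acinar marker, Cela1, was higher (0.48 ± 0.14, limma adjusted p = 0.0194). Immediate early genes lay above other genes by the set test (mean -0.06, camera p = 0.0150, estimated-correlation p = 0.518; median 0.20 after scaling, set call lost). In all 111 genes were higher and 3139 lower on the high-fat diet. The count was 848 (430 higher, 418 lower) without Mup and mt transcripts. Leaving out 1 library gave 1768 and 1383 without RD WT replicate 2 and 3 and 920 without HFD WT replicate 2. The median of all genes shifted by -0.29, and after scaling 391 genes were higher and 432 lower; Bst2 was no longer called lower.

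The interaction terms ask whether a genotype changed expression differently on the high-fat and on the regular diet, a positive value meaning a larger increase or smaller decrease on the high-fat diet. For LFKO 1 gene passed, Cyp2c69 (-3.40 ± 0.51, limma adjusted p = 0.0185); it was 36.6 ± 18.9 TPM in RD LFKO and 0.524 ± 0.336 TPM in HFD LFKO livers. Immediate early genes had lower values on the high-fat diet (median -0.89, camera p = 5.16e-12, estimated-correlation p = 0.0395), and the integrated stress and unfolded protein response list did too (median -0.13, camera p = 6.52e-04, estimated-correlation p = 0.0395; median -0.29 after scaling); 0 members of either were called, and both list calls held. Cholesterol synthesis and uptake genes had higher values: 0 of 22 were called higher and 0 lower (14 and 0 adjusted over the list alone). The median was 0.85 (camera p = 5.16e-12, estimated-correlation p = 0.476). Stellate cell and matrix genes (median 0.64, camera p = 7.45e-04, 5 adjusted over the list alone) and mt transcripts (median 0.39, camera p = 0.00110, set call lost after scaling) were above 0, with estimated-correlation p at least 0.663. The count of called genes became 0 with a pseudocount of 0.1, 4 with no filter, 4 (3 above, 1 below) at a mean TPM of at least 5, 2 after scaling and 4 with the compared groups alone in the fit. Without single libraries it was 28 (24 above, 4 below) and 2 without RD WT replicate 1 and 2, 5 and 0 without RD LFKO replicate 1 and 3, 0, 0 and 6 without HFD WT replicate 1, 2 and 3 and 90 (84 above, 6 below) and 0 without HFD LFKO replicate 1 and 2. The median of all genes shifted by 0.18, and limma gave 1292 genes at an unadjusted p under 0.05.

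For LPKO the interaction was above 0 for genes of cholesterol synthesis, the farnesyl diphosphate synthase gene Fdps (2.15 ± 0.36), the isopentenyl diphosphate isomerase gene Idi1 (1.96 ± 0.36) and Sqle (1.88 ± 0.36, limma adjusted p at most 0.0411). Fdps was 229 ± 94.2 TPM and 373 ± 59.9 TPM in RD WT and LPKO livers, and 29.2 ± 8.50 TPM and 230.2 ± 81.8 TPM in HFD WT and LPKO livers. Nat8 (2.22 ± 0.42) and the water channel gene Aqp4 (2.21 ± 0.39, limma adjusted p at most 0.0406) were also above 0. Below 0 were Ces4a (-2.17 ± 0.44), Mmp15 (-1.72 ± 0.29), the immune checkpoint gene Cd276 (-1.67 ± 0.27), Tgm1 (-1.62 ± 0.32) and Fkbp11 (-1.31 ± 0.25, limma adjusted p at most 0.0442). In the cholesterol list, 5 of 22 were called higher and 0 lower (18 and 0 adjusted over the list alone). The median was 1.01 (camera p = 1.83e-24, estimated-correlation p = 0.197). Kupffer cell markers (median 0.79, camera p = 4.19e-05, estimated-correlation p = 0.572) and stellate cell and matrix genes (median 0.58, camera p = 1.71e-06, estimated-correlation p = 0.319) were above 0 in the same term, with 0 called members. Mt transcripts (median 0.41, camera p = 9.96e-06, 1 adjusted over the list alone) were above 0 and immediate early genes (median -0.82, camera p = 7.32e-04, 3 adjusted over the list alone) below, with estimated-correlation p at least 0.366. In all 12 genes lay above and 6 below 0. Calls numbered 10 with no filter, 45 after scaling, 50 (22 above, 28 below) without Mup and mt transcripts and 14 (6 above, 8 below) with the compared groups alone in the fit. With 1 library left out there were 29, 8 and 6 without RD WT replicate 1, 2 and 3, 3, 21 (10 above, 11 below) and 7 without RD LPKO replicate 1, 2 and 3, 7, 4 and 9 without HFD WT replicate 1, 2 and 3 and 5, 9 and 60 without HFD LPKO replicate 1, 2 and 3.

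For LFPKO the interaction was below 0 for 3 genes, the metalloproteinase gene Mmp15 (-1.75 ± 0.29), Cd276 (-1.53 ± 0.27) and the deiodinase gene Dio1 (-1.29 ± 0.20, limma adjusted p at most 0.0459), with 6 above and 17 below after scaling and 796 genes at an unadjusted p under 0.05. Dio1 was 54.6 ± 13.7 TPM and 108 ± 3.64 TPM in RD WT and LFPKO livers, and 160.2 ± 19.5 TPM and 130.5 ± 18.2 TPM in HFD WT and LFPKO livers. Kupffer cell markers were above 0 (median 1.10, camera p = 9.28e-10, estimated-correlation p = 0.712), 10 of 14 when adjusted over the list alone and 0 over all genes. Cholesterol synthesis and uptake genes were above 0: 0 of 22 were called higher and 0 lower (10 and 0 adjusted over the list alone). The median was 0.61 (camera p = 9.28e-10, estimated-correlation p = 0.712). Stellate cell and matrix genes (median 0.47, camera p = 1.64e-04) and mt transcripts (median 0.36, camera p = 1.50e-04) were above 0, with estimated-correlation p at least 0.712. Called genes numbered 23 after scaling, 21 without Mup and mt transcripts and 0 with the compared groups alone in the fit. Leaving out 1 library gave 22 (15 above, 7 below), 0 and 0 without RD WT replicate 1, 2 and 3, 11, 7 and 0 without RD LFPKO replicate 1, 2 and 3, 0, 1 and 1 without HFD WT replicate 1, 2 and 3 and 1 (1 above, 0 below), 7 and 1 without HFD LFPKO replicate 1, 2 and 3.

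Calls in LFKO and LPKO livers were compared to see how far both deletions changed the same genes. On the regular diet 31 genes were higher and 15 lower in both LFKO and LPKO livers, while 13 moved in opposite directions. Independent lists of these sizes would share 3.97 and 1.47. The correlation of fold changes across genes, which are not independent replicates, was 0.364 and the covariance 0.0522. Simulated unchanged groups sharing a simulated WT group gave 0.504 and 0.0262. On the high-fat diet 196 genes were higher and 12 lower in both, and 27 opposite, against 48.4 and 0.868 for independent lists, with a correlation of 0.397 (simulated 0.502) and a covariance of 0.0486 (simulated 0.0261). Across diets, where no WT library is shared, LFKO on the regular and LPKO on the high-fat diet shared 15 higher and 8 lower genes with 13 opposite (4.07 and 0.711 for independent lists, covariance 0.0163). LFKO on the high-fat and LPKO on the regular diet shared 45 and 5 with 76 opposite (47.2 and 1.80 for independent lists, covariance -0.0152). The 3 WT libraries per diet cannot be divided into parts of at least 2, so part of the excess may come from the shared controls. After scaling the shared genes were 73 and 36 on the regular and 99 and 45 on the high-fat diet.

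Each genotype's calls on the regular diet mostly kept their sign on the high-fat diet, where no library is shared. Of the 176 LFKO calls, 152 (86.4%) had the same sign and 90 were called again. For LPKO 564 of 617 (91.4%) had the same sign and 182 were called again, and for LFPKO 701 of 786 (89.2%) and 198. Over all tested genes the shares with the same sign were 61.4%, 65.8% and 63.5%. Genes called in opposite directions numbered 0, 0 and 1.

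**Figure D4:**
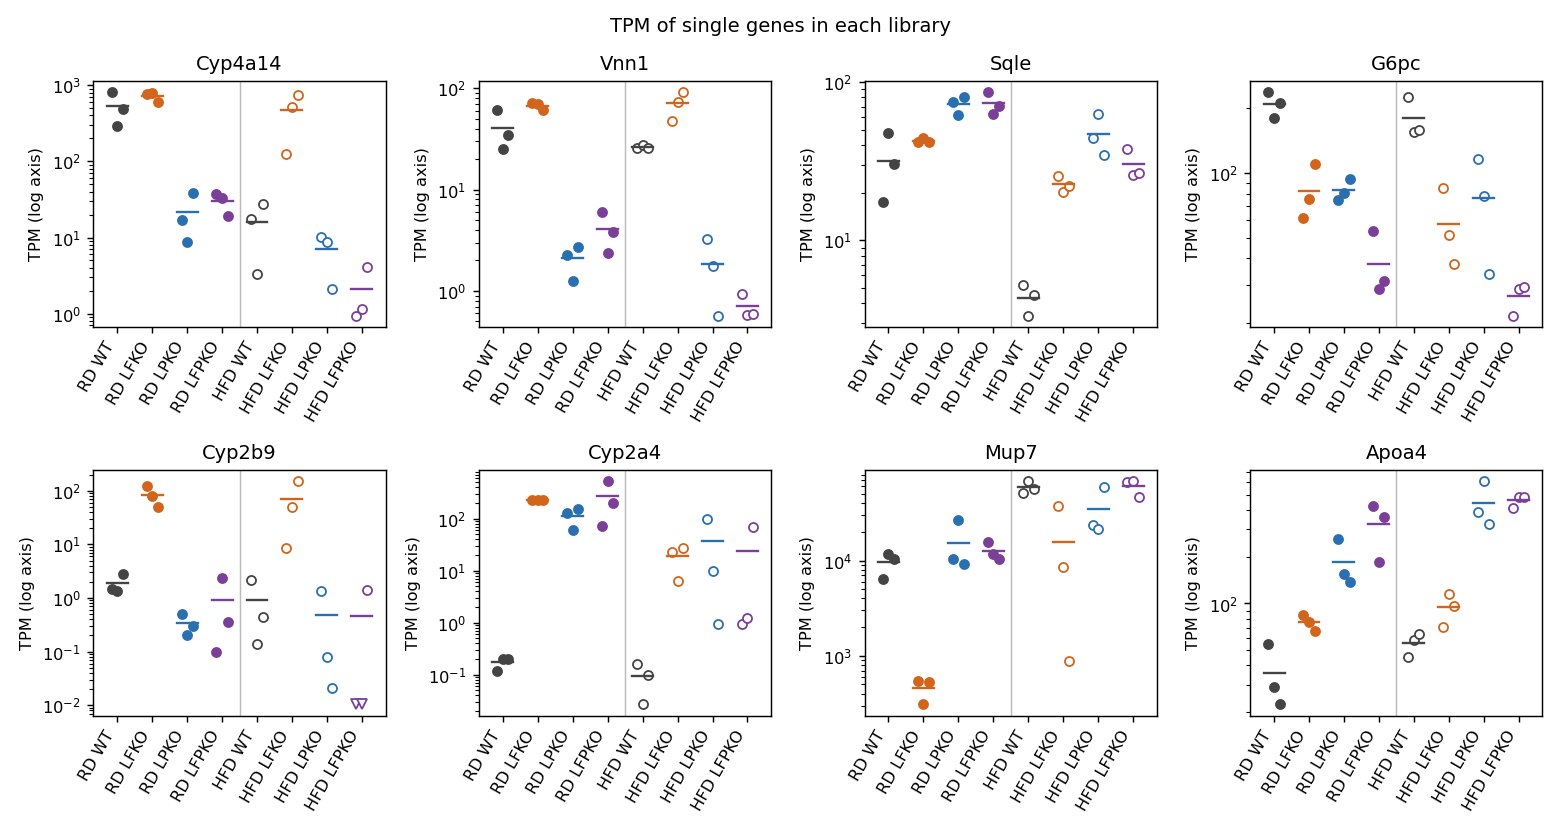
TPM on a log axis of 8 genes in each library, by group, with points for libraries and lines for means of 3; filled points are regular-diet and open points high-fat-diet libraries, and the triangles mark libraries in which Cyp2b9 was listed at 0. Cyp4a14 averaged 467 TPM in HFD LFKO and 2.08 TPM in HFD LFPKO livers.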

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

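Each result in this part was picked out because limma's test of a difference between effects passed its threshold, either between the double knockout and the sum of both single knockouts or between diets.

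On the regular diet, 27 genes departed from additivity. Above it were the major urinary protein genes Mup21 at 3.45 and Mup12 at 3.09, Nat8 at 2.93, Errfi1 at 1.76 and Nox4 at 1.0 on the log2 scale. Below it were the P450 genes Cyp2c40 at -4.81 and Cyp2c69 at -4.12, the histone gene H2ac18 at -2.60, Tcf24 at -2.52 and Jun at -2.40. Of 100 random splits of the 12 libraries into groups of 3, the real one included, 3 gave as many genes as the real 27, and the highest other split gave 109. Such splits also mix the genotypes, so they test no departure from additivity by itself, and a high count in one can come from the genotype effects.

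On the high-fat diet, 1179 genes departed from additivity, with the same limit from Albumin-Cre. The genes furthest above it were Mup7 at 4.08, Mup1 at 3.36, Mup-ps17 at 3.04, Mup12 at 2.90 and Mup14 at 2.86. Those furthest below it were Cyp4a14 at -6.13, Acot3 at -5.80, Hamp2 at -5.42, Cyp2b9 at -4.66 and Scd1 at -4.39, and the list of male-biased liver genes had a median of 1.27. Without Mup and mitochondrial-genome transcripts 341 genes lay above additivity and 287 below. Of the 100 splits, 1 gave as many genes, the real one, and the highest other gave 685. These splits mix the genotypes in the same way and exclude nothing on additivity.

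Between diets, 1 gene differed in the effect of LFKO, the P450 gene Cyp2c69 at -3.40. The immediate early list had a median of -0.89 and the integrated stress and unfolded protein response list one of -0.13. Of 100 splits, 18 gave at least 1 gene, so chance cannot be excluded for this count. For LPKO 18 genes differed, among them Nat8 at 2.22, Aqp4 at 2.21, Fdps at 2.15, Idi1 at 1.96 and Sqle at 1.88. Lower values were found for Ces4a at -2.17, Mmp15 at -1.72, Cd276 at -1.67, Tgm1 at -1.62 and Fkbp11 at -1.31. As many genes came from 9 of 100 splits, which does not exclude chance. For LFPKO 3 genes differed, Mmp15 at -1.75, Cd276 at -1.53 and Dio1 at -1.29, and 15 of 100 splits gave as many. The highest other splits gave 2837, 2493 and 3828 genes for LFKO, LPKO and LFPKO. Splits that call many times the real count point to a structure of the samples, and here they mix diets and genotypes, whose own effects are part of it.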

How the results depend on the processing

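The counts of called genes, of calls shared between LFKO and LPKO and the shares of calls keeping their sign between diets were computed again under each alternative, 1 choice at a time. With no library left out, 73 counts lay within 1.5 times the reported one, 26 were higher and 27 lower, and 15 shares moved by less than the spread and 6 by more. Leaving out Mup and mitochondrial-genome transcripts was chosen after seeing the data. The cause was not tested for the changes below, apart from the smaller number of genes tested at a mean TPM of at least 5.

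With a pseudocount of 0.1 the counts were 8 for LFPKO against LPKO on RD, 16 for additivity on RD and 0 for LFKO by diet. Without a filter they were 4 for LFKO by diet, 10 for LPKO by diet and 138 for shared calls on HFD, and the share of calls with the same sign on both diets became 85.9% for LPKO. At a mean TPM of at least 5 they were 97 for LFKO against WT on RD, 4 for LFPKO against LPKO on RD, 14 for additivity on RD, 21 for LFPKO against LPKO on HFD, 4 for LFKO by diet and 29 for shared calls on RD. After median-of-ratios scaling they were 389 for LFKO against WT on RD, 952 for LPKO against WT on RD, 1322 for LFPKO against WT on RD, 885 for LFPKO against LFKO on RD, 450 for LFKO against WT on HFD, 582 for LFPKO against WT on HFD, 126 for LFPKO against LPKO on HFD, 651 for additivity on HFD, 823 for the diet in WT, 2 for LFKO by diet, 45 for LPKO by diet, 23 for LFPKO by diet and 109 for shared calls on RD, and the share of calls with the same sign on both diets became 86.8% for LPKO and 86.2% for LFPKO. Without Mup and mitochondrial-genome transcripts they were 292 for LFKO against WT on RD, 949 for LPKO against WT on RD, 1225 for LFPKO against WT on RD, 992 for LFPKO against LFKO on RD, 440 for LFKO against WT on HFD, 587 for LFPKO against WT on HFD, 104 for LFPKO against LPKO on HFD, 628 for additivity on HFD, 848 for the diet in WT, 50 for LPKO by diet, 21 for LFPKO by diet, 77 for shared calls on RD and 129 for shared calls on HFD, and the share of calls with the same sign on both diets became 84.4% for LPKO and 85.9% for LFPKO. With the compared groups alone in the fit they were 431 for LFKO against WT on RD, 8 for LFPKO against LPKO on RD, 74 for additivity on RD, 140 for LFKO against WT on HFD, 147 for LPKO against WT on HFD, 165 for LFPKO against WT on HFD, 267 for LFPKO against LFKO on HFD, 5 for LFPKO against LPKO on HFD, 130 for additivity on HFD, 4 for LFKO by diet, 0 for LFPKO by diet, 173 for shared calls on RD and 37 for shared calls on HFD, and the share of calls with the same sign on both diets became 88.3% for LPKO.

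Dropping 1 library at a time gave counts of 77 to 173 for LFKO against WT on RD, 312 to 501 for LPKO against WT on RD, 417 to 645 for LFPKO against WT on RD, 278 to 445 for LFPKO against LFKO on RD, 7 to 18 for LFPKO against LPKO on RD, 8 to 27 for additivity on RD, 199 to 3501 for LFKO against WT on HFD, 198 to 889 for LPKO against WT on HFD, 217 to 370 for LFPKO against WT on HFD, 551 to 2438 for LFPKO against LFKO on HFD, 8 to 283 for LFPKO against LPKO on HFD, 431 to 2611 for additivity on HFD, 920 to 3590 for the diet in WT, 0 to 90 for LFKO by diet, 3 to 60 for LPKO by diet and 0 to 22 for LFPKO by diet. Replicate numbers did not pair the libraries: deviations from the group means correlated across genes at a mean of 0.00657 for the same number and -0.00324 for other numbers, and 9 of 24 libraries were closest to one of their own number. With the number as a block the counts were 8 for LPKO by diet and 8 for LFPKO by diet.

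Of the list calls made with the preset correlation, those that held with an estimated one were microsomal fatty acid hydroxylation in RD LPKO, RD LFPKO, HFD LFPKO and RD LFPKO against LFKO livers, mitochondrial fatty acid oxidation in HFD LFPKO and RD LFPKO against LFKO livers, other PPARα targets in the latter, cholesterol synthesis and uptake in HFD LPKO livers, male-biased genes in HFD LFKO livers and for additivity on HFD, and immediate early genes and the stress response in the LFKO by diet term. The male-biased list lay below other genes by the set test in the LFKO by diet term (camera adjusted p = 0.0247), although its median was 0.13. Without HFD LFKO replicate 3 the test turned the other way. With 1 library dropped its median ranged from -0.30 to 0.55, and the cause was not tested. Of 682 calls of genes named in the text, 642 were kept with a pseudocount of 0.1, 618 after median-of-ratios scaling, 544 without a filter, 651 with a replicate block and 499 with the compared groups alone in the fit. At a mean TPM of at least 5 there were 539 kept of 543 still tested, and without Mup and mitochondrial-genome transcripts 578 of 640. In these 7 settings 0 of the calls changed sign. Of 178 calls of lists, 152 were kept after scaling, 168 without a filter, 150 of 177 at a mean TPM of at least 5 and 144 of 170 without Mup and mitochondrial-genome transcripts. TPM carry no depth, so no limit of detection can be given, and a gene listed at 0 is not shown to be absent.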

Other observations

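Genes of the acute phase response were higher in HFD LFPKO than in HFD LFKO livers: 4 of 18 were called higher and 1 lower (6 and 2 adjusted over the list alone). The median was 0.33 (camera p = 4.38e-08, estimated-correlation p = 0.174).

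Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had group means of 16.1 to 19.5, 27.5 to 34.3, 3.44 to 4.64 and 3.40 to 5.45 TPM. Camera called oxidative stress response and circadian clock lists in 0 of 16 comparisons (adjusted p under 0.05). Nor did it call infiltrating monocytes and neutrophils (4 of 13 tested), cholangiocytes (3 of 9), adipocytes (3 of 8) or Y-linked genes (Xist untested). Lowest adjusted p, in order, were 0.0615, 0.125, 0.0769, 0.308, 0.0525 and 0.264.

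Of the tests below, those of the Mup and mitochondrial transcripts in the diet comparison, of reads shared by Cyp2a4 and Cyp2a5, and of a strain segment were chosen after the result was seen. In WT livers 96.6% of the calls between diets were lower on the high-fat diet. Poorer detection of weak transcripts is argued against, because 96.1% of calls were lower among the fifth of genes with the highest mean TPM. The share was 49.3% once Mup and mitochondrial-genome transcripts were left out. A larger share of TPM in a few abundant transcripts may therefore account for the excess of lower calls, as a hypothesis. A lower content of most messenger RNAs per liver on this diet stays open, since TPM are relative.

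The 3 HFD LFKO libraries lay apart, with Mup7 at 37746, 8551 and 892 TPM in replicates 1, 2 and 3. A wrong diet label is argued against, since their diet scores were 78.9%, 76.7% and 61.1% of the diet effect in LPKO and LFPKO livers, while RD LFKO libraries scored from -2.60% to 4.87%. The group's variance of 0.103 was 1.41 times the others' median (1.05 without Mup and mt transcripts). HFD LFPKO had 0.103 too, and 0.116 against 0.0845 without them. Shares of a few abundant transcripts stay a hypothesis for the spread. No biological cause was tested.

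A set of 11 genes separated all 6 WT from all 18 knockout libraries, among them Celf2, G6pc, Igfbp2 and Mup12, which were higher in WT, and Apoa4, Apof, Cyp2a4, Pls1, Serpina10 and Ube2l6, which were lower. Chance separates 0.00149% of genes this way, and of the other 15 choices of 1 group per diet 1 separated as many, the LFKO groups on both diets with 28, so the number alone does not set WT apart. Cyp2a4 held at least 0.170% of its TPM summed with Cyp2a5 in knockout and at most 0.0508% in WT libraries. Reads shared between them stay open, as their division is uncertain. A strain segment at 1 locus is argued against, with at most 2 genes on 1 chromosome. The Albumin-Cre transgene and the deletions cannot be told apart, because 0 groups carry the transgene without a deletion. A response to losing either factor stays open as well.

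Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. On the regular diet the real split and the highest other gave 176 and 2 genes for LFKO against WT, 617 and 2 for LPKO against WT, 786 and 2 for LFPKO against WT, 536 and 0 for LFPKO against LFKO, and 13 and 0 for LFPKO against LPKO. On the high-fat diet they gave 1420 and 1, 499 and 0, 326 and 4, 1117 and 1744, and 37 and 5. The diet comparison in WT livers gave 3250 and 0. In each of these the real split was the 1 with the most genes except for LFPKO against LFKO on the high-fat diet, where 2 of the 10 splits gave at least 1117. The other put HFD LFKO replicate 1 with HFD LFPKO replicates 1 and 2.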
